A study of Mus musculus with 16 samples.

How the data were processed

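RNA expression was measured on 16 single-colour Agilent microarrays, 1 array per labelled sample of retina and retinal pigment epithelium (RPE) of nm3342 mutant or wild-type mice. Per the labels' protocols, tissue came from both retinas and RPE at postnatal day 30 or 365, RNA was isolated with a mirVana kit, and labelling with Cy3 followed Agilent's Low Input Quick Amp procedure. The labels give the strain background C57Bl/6J and male sex for all 16 samples. They do not name the mutated gene, so no targeted gene was available as a check of the genotype labels.

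The scanner files hold fluorescence intensity per spot, background-subtracted and spatially detrended by Agilent Feature Extraction 11.0.1.1, per the file headers. The same files hold the median pixel intensity of each spot and of its local background and a mark for signal well above background, per the file headers. The authors also deposited a matrix of log2 values with 55821 entries, of which 55681 matched a probe of the scanner files. From its values, the deposited log2 matrix is quantile normalized between arrays, and the normalization software is not stated in the labels or the headers. The probe design refers to genome build mm9, per the file headers, and the only coordinates printed are those of that design.

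Everything that follows was computed from the scanner files. Each array held 62976 spots, of which 59305 were not controls, for 55681 probes. Spots marked as outliers on an array (93 to 136 per array) were left out, which left 20 missing values. The processed intensity was log2 transformed, the array's 75th percentile was subtracted, and the spots of a probe were averaged, so that a level of 0 is the 75th percentile of the array. Probe accessions were matched to the supplied RefSeq gene table (assembly GRCm38.p6, used only for names, chromosomes and gene order). Of the probes, 27235 were named by 1 gene each, covering 20660 genes, and 28446 had no match. Probes well above background on at least 4 of the 16 arrays were kept, without regard to group. This left 49230 probes, 25075 of them named. For each gene the probe with the highest mean over all 16 arrays was used, giving 19022 genes tested.

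One linear model per gene was fitted with limma 3.58.1 (R 4.3.3, data.table version 1.17.8, statmod version 1.5.0), with 4 group means and moderated variances over all 16 arrays. The 5 contrasts were mutant against wild type at 1 month, the same at 1 year, the difference between those effects, and 1 year against 1 month in each genotype. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 19022 genes, two-sided. All p-values of genes are from limma. Errors beside a log2 change are the model's standard errors with 4 arrays per group, and errors beside a group mean are SDs. Where a probe was well above background on none of the 4 arrays of 1 group, the fold is given as a lower bound, computed against the lowest signal called well above background on each of those arrays or the probe's own signal, whichever was higher.

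The 29 gene lists, for cell types of the retina, RPE, neighbouring tissues and processes, were written before the data were examined. They hold 404 genes, of which 399 were on the array and 395 were tested, and 6 genes stand in 2 lists each. C1qa, C1qb and C1qc stand in the microglia and complement lists and C4b in the gliosis and complement lists. Rlbp1 stands in the Müller glia and RPE lists and Tfap2b in the amacrine and horizontal cell lists. List shifts were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 29 lists within each contrast. Camera compares a list with the other genes. The alternatives were camera with an estimated correlation and fry, whose directional test asks whether the genes of a list move, on balance, one way. Counts of members are given over all genes tested and adjusted over the list alone. List means per array were compared between groups by exact permutation, where the smallest p for 4 against 4 arrays is 0.0286.

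The genes named in the text were fixed by a rule written before the data were examined. For each genotype comparison these are the 8 called genes with the largest fold in each direction whose 4 mutant arrays all lay on one side of the 4 wild-type arrays, leaving out clone, RIKEN, Gm and LOC names. Of each list they are the first 2 members as written and up to 4 further called members with the smallest adjusted p. For the other contrasts they are the 5 largest in each direction, for the difference between effects without the condition on sides. Genes singled out otherwise are said to be chosen after their values were seen.

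The labels give no batch. The scanner files show 2 slides of 8 arrays, each with 2 arrays of every group, so slide and group are balanced. Slide entered as a block in an alternative fit. Row and genotype are not balanced: on slide 2 every mutant array lay in row 2 and every wild-type array in row 1. Between slides 83 genes differed (1810 at an unadjusted p under 0.05), and with limma 0 genes differed with the row on the slide (1423 at an unadjusted p under 0.05). Because row and genotype cannot be told apart on slide 2, the 0 does not exclude an effect of row. The replicate numbers did not pair samples across groups: of the 4 same-numbered pairs in each of 4 pairs of groups, at most 1 had correlated deviations above 0.1, and the values ran from -0.54 to 0.17. A fit with replicate number as a block is therefore given only among the alternatives.

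The fit was tested on simulated data before use, with 200 of the 19022 genes changed between the genotypes at 1 month. It recovered 52% of the genes changed 1.5-fold, 74% at 2-fold, 90% at 3-fold and 92% at 4-fold (50 genes each). Of 167 calls 13 were false (7.78%), and 0 genes were called at 1 year, where nothing was changed. The list with a simulated shift was called, and 0 of the 28 other lists were. The simulated genes varied independently of each other, so this does not test the list calls for genes that vary together.

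The alternatives chosen in advance were normexp background correction (offset 50), quantile normalization, the deposited matrix, no filter and a filter on all 16 arrays, slide as a block, slide with array row, replicate number as a block, only the groups compared, array weights, a trended and robust variance, the mean of a gene's probes, every probe on its own, a further 2-fold minimum, and leaving out each array in turn. The intended normexp input was the mean spot signal, which the scanner files do not hold, so the median spot signal took its place. Alternatives added after the data were seen were each slide alone, covariates for lens, muscle, erythrocyte and cornea lists, a covariate for the mean of the RPE, melanin, matrix and endothelial lists, leaving out 3 arrays that stood apart in lens, muscle or cornea genes, leaving out 3 arrays with a female pattern of sex-linked genes, that pattern as a covariate, and the mean of the olfactory receptor probes as a covariate. Probes without a gene name were tested apart with the same model. No array was left out of the results given first.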

Results

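The 16 arrays cover 4 groups of 4 mice each: nm3342 mutants and wild types at 1 month and at 1 year. The series title describes the nm3342 mouse as a potential model of serous retinal detachment, in which fluid gathers between the retina and the RPE. Each sample held RNA of retina and RPE together, so a level cannot be assigned to either tissue. Signal was well above background for 82.1% to 89.6% of the non-control spots of an array. The group means were 85.1% ± 3.19 in the 1-month mutants, 86.0% ± 2.06 in the 1-month wild types, 85.4% ± 1.08 in the 1-year mutants and 85.1% ± 2.42 in the 1-year wild types (SD, n = 4). The 75th percentile of the processed signal ran from 603 to 994, and at most 2 spots per array were saturated. With 4 arrays per group, the number of arrays limits the precision.

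Sex-linked genes did not match the label of male sex on 3 arrays: those labelled mutant 1-month replicates 2 and 3 and mutant 1-year replicate 1. On these 3 arrays Xist, the RNA that silences an X chromosome in females, lay between -0.38 and -0.03 on the log2 scale, against -8.61 to -5.68 on the other 13. The Y-linked gene Ddx3y lay between -8.47 and -8.13 on the 3 arrays and between 0.69 and 1.19 on the other 13. The 8 wild-type arrays all had the male pattern. Of the genes called between genotypes, 26 at 1 month and 1 at 1 year lie on the X or Y chromosome, all of them on X. The X chromosome holds 3.75% of the genes tested. It held 5.02% of the 1-month calls (adjusted Fisher's exact p = 0.363) and 0.61% of the 1-year calls. A further feature of the 1-month arrays did not follow genotype. The mean of 1160 olfactory receptor probes was -6.18, -6.04, -6.09 and -5.49 on mutant replicates 1 to 4 and -5.29, -5.75, -5.82 and -6.17 on wild-type replicates 1 to 4. Over all 16 arrays, 42.5% to 62.8% of these probes were marked well above background.

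**Figure D1:**
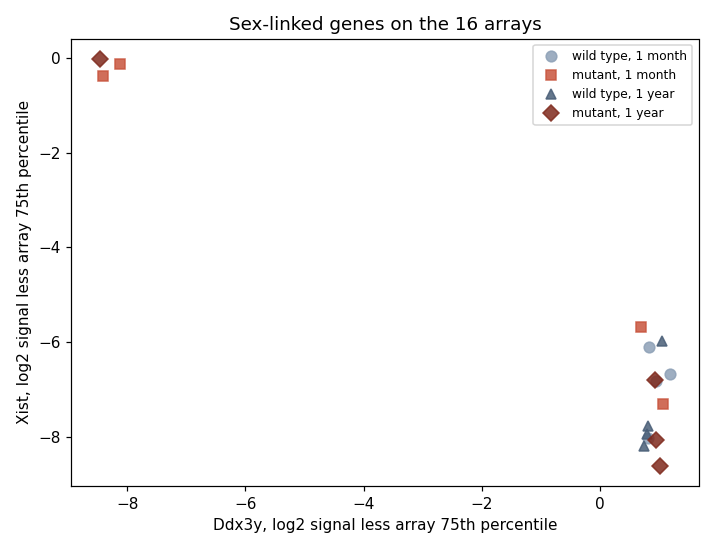
Xist against Ddx3y, both as log2 signal less the array's 75th percentile, with 1 point per array for the 16 arrays and the 4 groups marked. The 3 mutant arrays at Xist levels of -0.38 to -0.03 lack Ddx3y signal, and the other 13 arrays have Ddx3y levels of 0.69 to 1.19.

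At 1 month, the comparison of mutant with wild type asks how the mutant tissue differs early in life. In the mutant 12 of 21 genes of the interferon and antigen presentation list were higher, 10 of 24 of microglia and macrophages, 5 of 10 of melanin synthesis, 4 of 15 of the RPE and 7 of 21 of the matrix. As lists these were called by camera at its preset correlation but not with an estimated correlation (adjusted p = 0.166, 0.225, 0.269, 0.415 and 0.269 with an estimated correlation). The collagen gene Col3a1 rose by 2.35 ± 0.21 on the log2 scale (a 5.11-fold difference, adjusted p = 5.07e-05), and Retnla, a secreted product of alternatively activated macrophages, by 2.70 ± 0.31 (adjusted p = 0.000316). Omg, which encodes the oligodendrocyte-myelin glycoprotein, fell by 2.45 ± 0.14 (adjusted p = 8.11e-07), and Etnppl, a phospholyase of phosphoethanolamine, fell by 2.01 ± 0.14 (adjusted p = 2.26e-06). By the rule that chose them, every gene named for its fold lay on one side in all 4 mutant arrays relative to all 4 wild-type arrays.

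Of 19022 genes, 518 were called at 1 month, 386 higher and 132 lower, and 99 of these differed at least 2-fold. The median log2 change of all genes was 0.02. In 8.53% of genes the groups did not overlap, where chance gives 2.86%. Beside Col3a1 and Retnla, the largest rises included S100a8 (3.26 ± 0.71) and S100a9 (3.02 ± 0.73), subunits of a neutrophil calcium-binding protein, the keratin Krt23 (8.03-fold) and the neutrophil chemokine Cxcl5 (2.18 ± 0.43). S100a8 was well above background on 2 of the 4 wild-type arrays. Atp1b4 was at least 1.89-fold higher. With clone and RIKEN names left out by the naming rule, the largest falls beside Omg and Etnppl were in the amylases Amy1 (-2.04 ± 0.24) and Amy2a5 (-1.93), the protein kinase C gene Prkcq (-1.58 ± 0.10), Adamts18 (-1.56), Folh1 (-1.47) and Selenbp1 (-1.47).

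All 21 measured members of the interferon and antigen presentation list had positive changes at 1 month: 12 passed the test over all genes, 20 passed adjusted over the list alone, and the median was 0.76 (camera adjusted p = 4.32e-20, adjusted p = 0.166 with an estimated correlation). Gbp3, a guanylate-binding protein, rose by 2.01 ± 0.24 (adjusted p = 0.000378), Bst2, which tethers budding virus, by 1.39 ± 0.19, Oasl2 by 1.37, and the class II molecule H2-Ab1 by 1.06. The class I genes B2m (0.82) and H2-K1 (0.58) also rose. The list median was 0.90 on slide 1 and 0.73 on slide 2. Of the 24 members of the microglia and macrophage list, 10 rose and 13 did so adjusted over the list alone, with a median of 0.45 (camera adjusted p = 2.56e-11, adjusted p = 0.225 with an estimated correlation). Aif1, a marker of microglia, rose by 1.03 ± 0.13, the receptor gene Csf1r by 0.73 ± 0.09, Adgre1 by 1.09, Itgax by 1.04 and Laptm5 by 0.86. Of the other Csf1r probes 1 was 0.94 and 1 went the other way (-0.49, unadjusted p = 0.04). The microglia list median was 0.51 on slide 1 and 0.54 on slide 2.

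The matrix list had 7 of 21 members higher at 1 month, 11 adjusted over the list alone, and a median of 0.63 (camera adjusted p = 1.03e-08, adjusted p = 0.269 with an estimated correlation). They include Postn (1.78 ± 0.19), Col8a1 (0.98) and Col5a1 (0.83), while Col1a1 was 2.30-fold (adjusted p = 0.0834) and did not pass. The melanin list had 5 of 10 members higher, 9 adjusted over the list alone, and a median of 0.60 (camera adjusted p = 4.19e-08, adjusted p = 0.269 with an estimated correlation), among them Slc45a2 (1.07), Pmel (0.94), Gpr143 (0.86), Tyrp1 (0.83) and Tyr (0.52). Of the 15 members of the RPE and visual cycle list 4 rose, 8 adjusted over the list alone, and the median was 0.40 (camera adjusted p = 1.32e-05, adjusted p = 0.415 with an estimated correlation). The lactate transporter Slc16a8 (0.80), Ttr (0.72), Rdh5 (0.66) and Rlbp1 (0.58) rose, whereas the retinoid isomerase gene Rpe65 was -0.18 ± 0.17 (adjusted p = 0.684) and Lrat 0.02. With the array mean of the RPE, melanin, matrix and endothelial lists as a covariate, the microglia median was 0.17 (adjusted p = 0.111) and the interferon median 0.47 (adjusted p = 3.00e-07).

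Cytokine and chemokine genes had a median of 0.60, with 2 of 15 higher and 6 adjusted over the list alone (camera adjusted p = 0.000364, adjusted p = 0.269 with an estimated correlation). They are Ccl12 (1.35) and Cxcl10 (1.72), and the median was 0.17 on slide 1 and 1.07 on slide 2, 0.36 without mutant replicate 3 and 0.38 without wild-type replicate 4. In the complement list 3 of 16 rose and 4 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.00515, adjusted p = 0.415 with an estimated correlation): factor B gene Cfb (1.06), C1qa (0.55) and C1qc (0.57). C1qa and C1qc are also members of the microglia and macrophage list, so the 2 lists are not separate results. The complement median was -0.13 with the RPE, melanin, matrix and endothelial covariate. Without mutant replicate 4 the complement and muscle lists lost their calls, with medians of 0.21 and 0.50. The muscle list, from tissue next to the eye, had a median of 0.66 with 1 of 14 higher, Acta1 (1.81), and 4 adjusted over the list alone (camera adjusted p = 0.00058, adjusted p = 0.544 with an estimated correlation).

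Of the clock list 2 of 12 genes fell, Per1 (-1.23 ± 0.12, adjusted p = 0.000108) and Ciart (-0.67 ± 0.11), both also adjusted over the list alone (median -0.07, camera adjusted p = 0.0165, adjusted p = 0.269 with an estimated correlation). The clock call was lost without mutant or wild-type replicate 4, with a largest adjusted p of 0.0559. A further 6 lists were called by camera with no member past the test over all genes. The cholesterol synthesis list had a median of 0.14 (camera adjusted p = 0.00862, adjusted p = 0.544 with an estimated correlation). The lens list had a median of -0.83 (camera adjusted p = 0.0367, adjusted p = 0.659 with an estimated correlation), with 0.45 on slide 1 and -2.58 on slide 2. The erythrocyte median was 2.13 (camera adjusted p = 0.0367, adjusted p = 0.463 with an estimated correlation) and the immediate early median -0.31 (camera adjusted p = 0.0392, adjusted p = 0.463 with an estimated correlation). The lymphocyte median was -0.21 (camera adjusted p = 0.0486, adjusted p = 0.544 with an estimated correlation). The endoplasmic reticulum stress median was 0.16 (camera adjusted p = 0.0486, adjusted p = 0.641 with an estimated correlation). Adjusted over the list alone, 2 erythrocyte and 2 endoplasmic reticulum stress genes passed. Each of these 6 calls was lost when some single array was left out. The cholesterol call was lost without wild-type replicate 1 (lowest median 0.10). The lens call was lost without mutant replicates 1 or 3 or wild-type replicate 3 (highest median -0.14), and the median was -1.65 without mutant replicate 4. The erythrocyte call was lost without mutant replicate 4 or wild-type replicates 2 or 4 (largest adjusted p = 0.243, lowest median 1.202). The immediate early call was lost without mutant replicate 4 or wild-type replicates 2, 3 or 4 (highest median -0.22). The lymphocyte call was lost without mutant replicates 1, 2 or 3 or wild-type replicates 1 or 3 (highest median -0.12). The endoplasmic reticulum stress call was lost without mutant replicates 1, 2 or 3 or wild-type replicates 1, 2 or 4 (lowest median 0.14).

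The photoreceptor and other neuronal lists were not called at 1 month. The rod median was 0.06 (adjusted p = 0.232), with Gnat1 at 0.22 ± 0.06, and 0 of 24 members called. Cones had a median of 0.00, amacrine cells -0.01, horizontal cells -0.12 and ganglion cells 0.02, where camera's direction was down, each with 0 members called. In the bipolar list (median 0.07) the glutamate receptor gene Grm6 (0.54) and Nyx (0.54) rose, and in the Müller glia list (median -0.01, mean 0.10) Rlbp1 and Abca8a (0.57). With the female or male pattern as a covariate Grm6 was 0.46 (adjusted p = 0.067) and Nyx 0.38 (adjusted p = 0.154), neither called. In the RPE junction and transport list (0.07) Cdh3 (0.70) and Bsg (0.43) rose. The growth factor receptor gene Kdr (0.68) rose in the endothelial list (0.20), and Ripk3 (1.01) in the cell death list (0.23). The gliosis list (median 0.21, adjusted p = 0.0669) had 1 gene higher, Gbp2 (0.96), and 1 lower, Cebpd (-1.21), and Gfap was -0.63 ± 0.26 (adjusted p = 0.264). The medians were 0.13 for oxidative stress, 0.09 for the cell cycle, with 1 member higher adjusted over the list alone, and 0.20 for cornea.

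**Figure D2:**
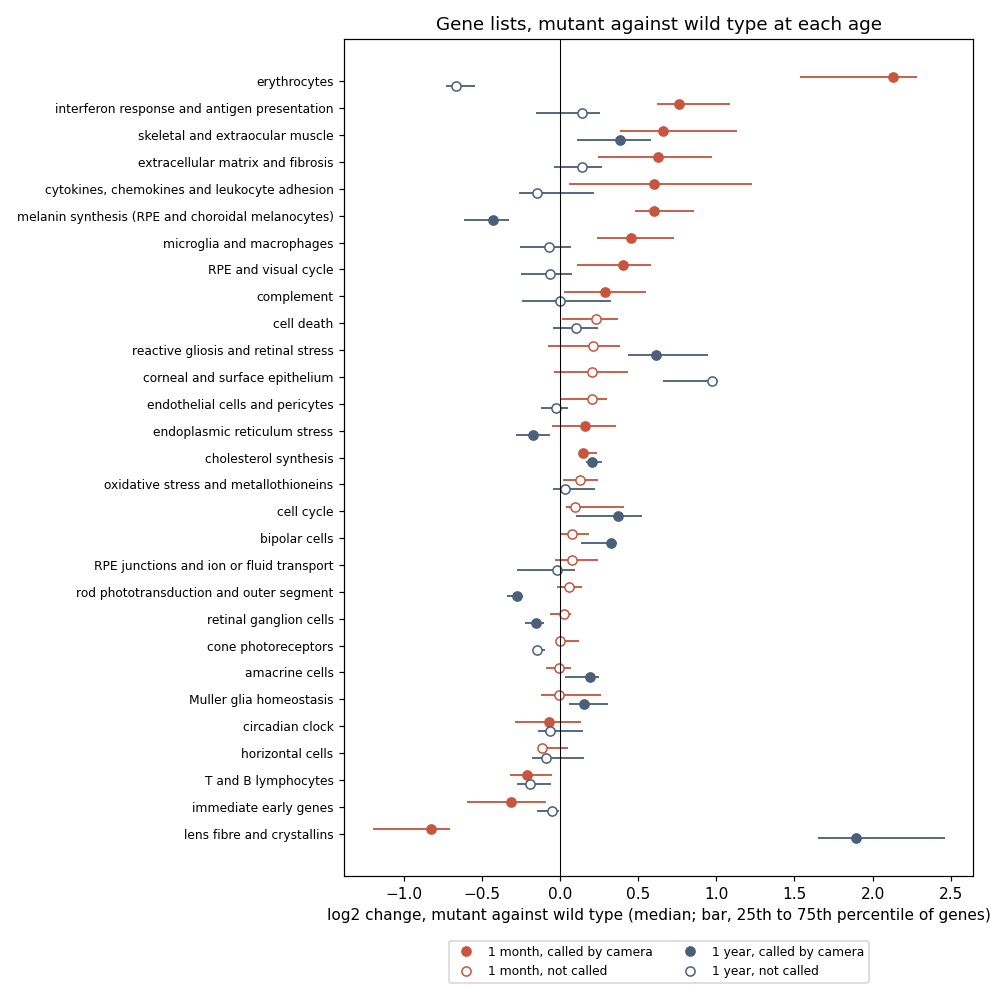
Median log2 change, mutant less wild type, of each of the 29 gene lists at 1 month and at 1 year, with bars from the 25th to the 75th percentile of its genes and filled points for lists called by camera at the preset correlation. The interferon list has medians of 0.76 at 1 month and 0.14 at 1 year, the gliosis list 0.21 and 0.61, and the rod list 0.06 and -0.28.

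The 1-month count was 498 with slide as a block, 1 on slide 1 alone and 17 on slide 2 alone (2 arrays per group each). Without the 3 arrays with the female pattern it was 133, and with that pattern as a covariate 244. With the RPE, melanin, matrix and endothelial covariate 22 genes were called, 4 higher and 18 lower, among them Omg, Etnppl, Prkcq, Folh1, Selenbp1 and Per1. Col3a1 and Kdr are also in that count, but they belong to lists that form the covariate. Of the calls 74.5% were higher, against 43.2% of 1125 with the lens, muscle, erythrocyte and cornea covariates, 59.7% with array row and 59.9% without mutant replicate 4. Leaving out 1 array moved the count to 227, 309, 299 and 931 without mutant replicates 1 to 4, and to 277, 325 and 290 without wild-type replicates 1 to 3. Of the 56 named calls at 1 month 35 held in every fit without 1 array. The 21 others were S100a8, S100a9, Nyx, Abca8a, Cebpd, Slc16a8, Ttr, Rdh5, Tyr, Tyrp1, Slc45a2, Gpr143, Pmel, Cdh3, Bsg, C1qa, C1qc, H2-K1, Cxcl10, Acta1 and Ripk3. With the female or male pattern as a covariate 37 of the 56 held. Of the 35, Cxcl5 (adjusted p = 0.0552) and Grm6 (adjusted p = 0.067) lost the call in that fit.

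At 1 year, the same comparison asks how the genotypes differ in older animals. In the list of reactive gliosis and retinal stress 6 of 20 genes were higher in the mutant (adjusted p = 0.0143 with an estimated correlation), and in the rod list 1 of 24 was lower (adjusted p = 0.308 with an estimated correlation). Edn2, the endothelin made by stressed photoreceptors, rose by 4.06 ± 0.27 (16.6-fold, adjusted p = 8.01e-07) and Lcn2, an iron-siderophore binding protein of the acute phase, by 2.67 ± 0.30 (adjusted p = 0.000378). Calca, the precursor of calcitonin and its related peptide, rose by 2.94 ± 0.14 (adjusted p = 9.58e-08). Rod transducin Gnat1 fell by 0.33 ± 0.06 (adjusted p = 0.0246), and 23 of the 24 measured rod genes had negative changes.

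Of 19022 genes, 163 were called at 1 year, 116 higher and 47 lower, 38 of them at least 2-fold, with a median log2 change of all genes of -0.01. The groups did not overlap in 7.83% of genes. Beside the genes above, the chemokine Ccl28 (2.21 ± 0.16), Cuedc1 (2.17 ± 0.13) and Adam7 (1.78 ± 0.17) rose, and Tcstv1 was at least 2.84-fold higher. The other Calca probe was 0.04 (unadjusted p = 0.791). Under the naming rule, which leaves out clone and RIKEN names, the largest falls were in the serine protease gene Prss56 (-2.55 ± 0.43), Omg (-2.19 ± 0.14, rounded from -2.185), Prkcq (-1.87 ± 0.10), the oxygen sensor gene Egln1 (-1.67 ± 0.17), Wfikkn2 (-1.40 ± 0.21), the lysosomal glucosidase gene Gaa (-1.39 ± 0.08), Il7r (-1.19 ± 0.22) and Meox1 (-1.19 ± 0.22).

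In the gliosis list 6 of 20 genes rose. Adjusted over the list alone, 13 were higher and 1 lower. Its median of 0.61 was the 1 list call at 1 year that held with an estimated correlation (camera adjusted p = 5.57e-17, adjusted p = 0.0143 with an estimated correlation). Beside Edn2 and Lcn2, C4b rose by 1.25 ± 0.17, Stat3 by 0.56 and the oncostatin M receptor gene Osmr by 0.62, while Gfap, the intermediate filament of reactive glia, was 1.14 ± 0.26 (adjusted p = 0.0576). Without wild-type replicate 4 Gfap was 1.28 ± 0.27 (adjusted p = 0.0359). The gliosis median was 0.70 on slide 1 and 0.56 on slide 2. The rod list had a median of -0.28, with 1 of 24 lower over all genes and 19 lower adjusted over the list alone (camera adjusted p = 2.26e-15, adjusted p = 0.308 with an estimated correlation). The rod median was -0.34 on slide 1 (-0.345) and -0.23 on slide 2. Gnat1 held its call in 1 of the 8 fits without 1 array, with a largest adjusted p of 0.0897.

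The melanin list had a median of -0.43, with 0 of 10 called and 5 lower adjusted over the list alone (camera adjusted p = 3.44e-05, adjusted p = 0.573 with an estimated correlation), and Tyrp1 was -0.75 ± 0.20 (adjusted p = 0.111). Bipolar genes had a median of 0.32, 0 called and 6 higher adjusted over the list alone (camera adjusted p = 5.90e-05, adjusted p = 0.573 with an estimated correlation). The Müller glia list had a median of 0.15 with 1 of 12 higher, the thyroid hormone binding protein Crym (0.91 ± 0.11), and 2 adjusted over the list alone (camera adjusted p = 0.00145, adjusted p = 0.573 with an estimated correlation). The remaining called lists had no member past the test over all genes or adjusted over the list alone. The lens median was 1.90 (camera adjusted p = 5.57e-06, adjusted p = 0.667 with an estimated correlation) and the cholesterol synthesis median 0.21 (camera adjusted p = 0.000241, adjusted p = 0.573 with an estimated correlation). Without 1 array the lens median was 1.15, 0.78 and 1.18 (mutant replicates 3 and 4, wild-type replicate 2), and it was 3.17 on slide 1 and 0.86 on slide 2 (adjusted p = 0.0991). The cholesterol median was 0.12 without mutant replicate 2 and 0.14 without wild-type replicate 3. The endoplasmic reticulum stress median was -0.17 (camera adjusted p = 0.00551, adjusted p = 0.667 with an estimated correlation) and the amacrine median 0.19 (camera adjusted p = 0.00768, adjusted p = 0.573 with an estimated correlation). The muscle median was 0.38 (camera adjusted p = 0.0294, adjusted p = 0.733 with an estimated correlation). The cell cycle median was 0.37 (camera adjusted p = 0.0336, adjusted p = 0.674 with an estimated correlation) and the ganglion cell median -0.16 (camera adjusted p = 0.0432, adjusted p = 0.733 with an estimated correlation). Of these, amacrine cells lost the call without mutant replicate 1 (largest adjusted p = 0.0622) and endoplasmic reticulum stress without wild-type replicates 1 or 3 (largest adjusted p = 0.0693). The muscle call was lost without mutant replicates 2 or 4 or wild-type replicates 2 or 3 (largest adjusted p = 0.777, lowest median 0.03). The cell cycle call was lost without mutant replicate 2 or wild-type replicates 2 or 3 (largest adjusted p = 0.55, lowest median 0.10). The ganglion cell call was lost without wild-type replicates 2, 3 or 4 or mutant replicate 2 (largest adjusted p = 0.855), and without mutant replicate 2 the median was 0.02.

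The lists that moved at 1 month were mostly not called at 1 year. The interferon median was 0.14 (adjusted p = 0.303) and the microglia median -0.07, with 1 gene higher, the fractalkine receptor gene Cx3cr1 (0.89, adjusted p = 0.0497). Complement had a median of 0.00 (mean 0.23), with the inhibitor Cfi (1.68 ± 0.19, adjusted p = 0.000307) and C4b higher and, adjusted over the list alone, 3 higher and 1 lower. The median was 0.14 for matrix (2 members higher adjusted over the list alone), -0.15 for cytokines and -0.06 for the RPE list, where Rpe65 was -0.66 ± 0.17 (adjusted p = 0.0992). It was -0.02 for RPE junctions, -0.67 for erythrocytes, 0.97 for cornea, -0.20 for lymphocytes (-0.195), 0.10 for cell death and 0.03 for oxidative stress. It was -0.06 for immediate early genes (-0.055) and -0.09 for horizontal cells, where camera's direction was up. In 3 more lists 1 gene each was called: Gnb3 (0.73) among cones (median -0.15, mean -0.05), Kdr (0.71) among endothelial genes (median -0.03, mean 0.00) and Per1 (-0.78) in the clock list (median -0.06).

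**Figure D3:**
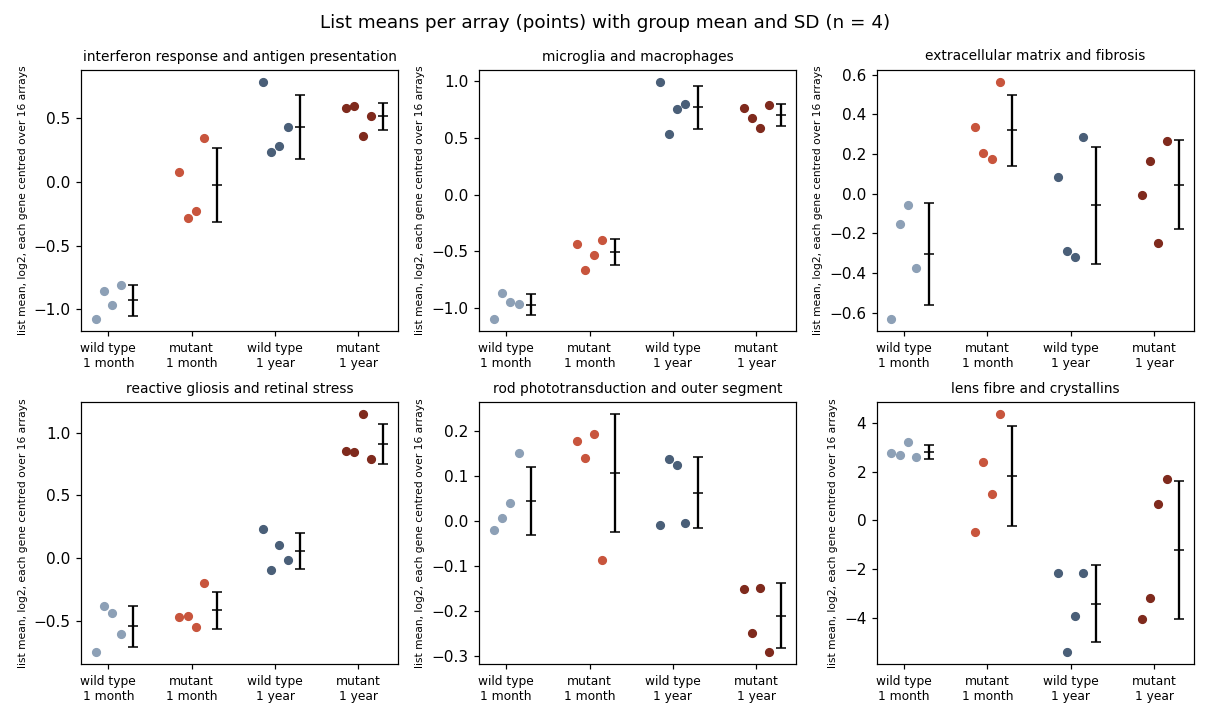
Mean log2 level of 6 gene lists on each of the 16 arrays, each gene centred on its mean over all arrays, with the group mean and SD (n = 4). At 1 month the interferon and microglia lists of the 4 mutant arrays lie above those of the 4 wild-type arrays, and at 1 year the gliosis list lies above and the rod list below.

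The 1-year count was 154 with slide as a block, 10 on slide 1 alone and 12 on slide 2 alone. Without the 3 arrays with the female pattern it was 78, with lens, muscle, erythrocyte and cornea covariates 31, and without 1 array 96, 87 and 92 (mutant replicates 1, 3 and 4) or 84, 95 and 308 (wild-type replicates 2, 3 and 4). Of the 26 named calls 19 held in every fit without 1 array, and the 7 others were Tcstv1, Il7r, Meox1, Gnat1, Gnb3, Osmr and Cx3cr1.

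**Figure D4:**
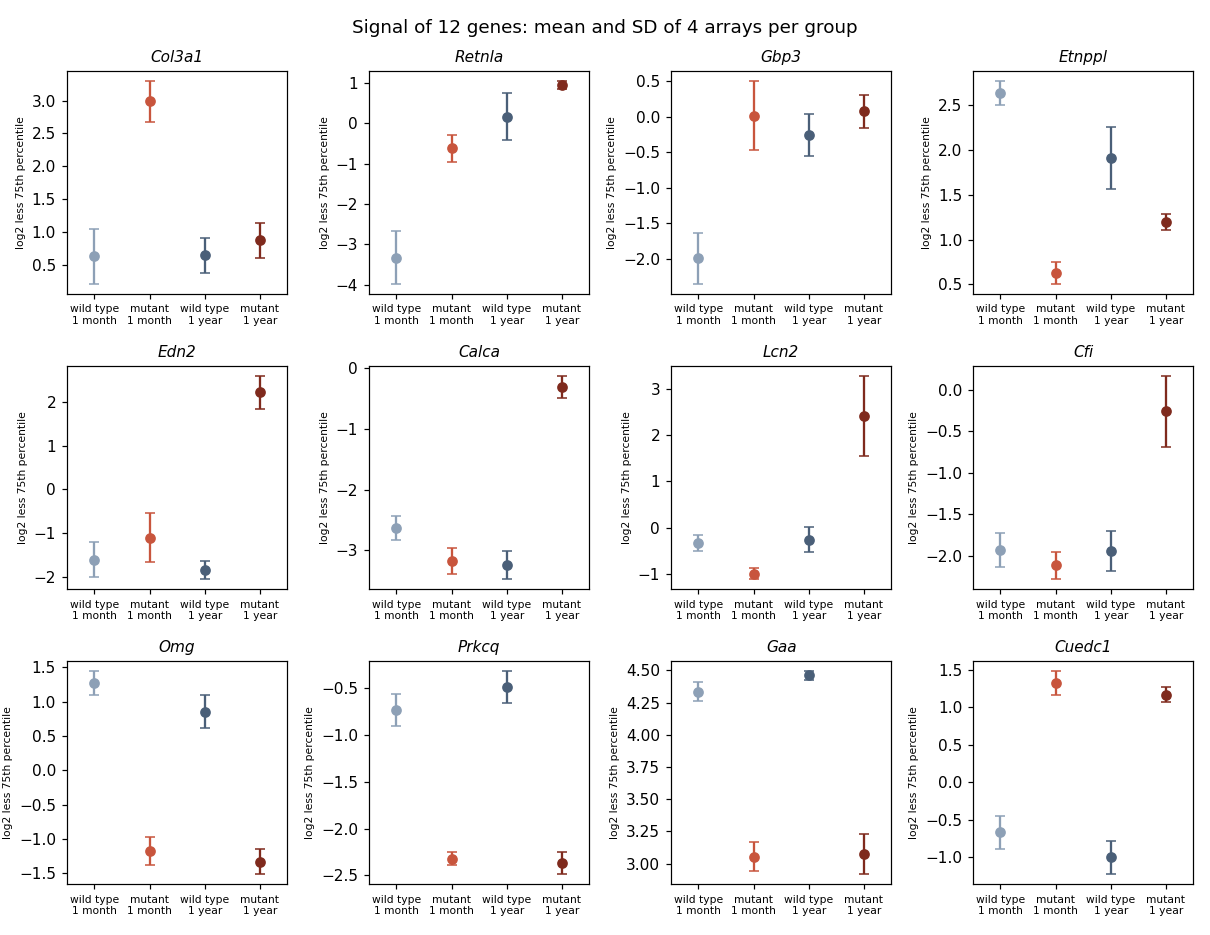
Mean log2 level less the array's 75th percentile, with SD (n = 4), of 12 genes in the 4 groups. Col3a1 is highest in the 1-month mutants at 2.99, Edn2 in the 1-year mutants at 2.21, and Omg is lower in the mutants at both ages.

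The difference between the mutant effects at the 2 ages was itself tested. Calca (3.49 ± 0.20, adjusted p = 1.08e-06), Edn2 (3.56 ± 0.37) and Lcn2 (3.33 ± 0.43) had larger mutant effects at 1 year, as did Ccl28 (2.10 ± 0.23, from 2.095) and Cebpd (2.08 ± 0.42). The other Calca probe was 0.03 for this difference (unadjusted p = 0.894). Col3a1 (-2.13 ± 0.30), Pirb, an inhibitory receptor of myeloid cells (-1.90 ± 0.18), Col14a1 (-1.82 ± 0.27), Slc45a2 (-1.78 ± 0.30) and Prss56 (-3.05 ± 0.61, from -3.045) had effects at 1 year below those at 1 month. The mean level of Pirb in wild types was -3.61 at 1 month and 0.00 at 1 year, and in mutants -2.23 and -0.51. In all, 80 genes differed, 27 upward and 53 downward.

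The mutant effect on the interferon list differed between the ages by a median of -0.74, with 4 of 21 genes called and 10 adjusted over the list alone (camera adjusted p = 2.46e-13, adjusted p = 0.133 with an estimated correlation). The melanin list differed by -0.90 (2 of 10 called, 10 adjusted over the list alone, camera adjusted p = 2.67e-13, adjusted p = 0.133 with an estimated correlation), and the microglia list by -0.47 (3 of 24 called, 14 adjusted over the list alone, camera adjusted p = 1.30e-11, adjusted p = 0.133 with an estimated correlation). Rod genes differed by -0.33 (1 of 24 called, 12 adjusted over the list alone, camera adjusted p = 3.14e-12, adjusted p = 0.182 with an estimated correlation), and gliosis genes by 0.39 (3 of 20 called, camera adjusted p = 1.85e-07, adjusted p = 0.133 with an estimated correlation). With the RPE, melanin, matrix and endothelial covariate the microglia median was -0.18 (adjusted p = 0.162) and the interferon median -0.41 (adjusted p = 0.0111). With the lens, muscle, erythrocyte and cornea covariates the gliosis median was 0.15 (adjusted p = 0.147), which was not called. The count of 80 was 112 with slide as a block, 1 on slide 1 and, with limma, 0 on slide 2 alone (1285 at an unadjusted p under 0.05), and 12 without the 3 arrays with the female pattern. Without 1 array it was 33, 46 and 150 (mutant 1-month replicates 1, 3 and 4), 40 and 35 (mutant 1-year replicates 1 and 3), 45, 43 and 47 (wild-type 1-month replicates 1 to 3) and 43, 42 and 195 (wild-type 1-year replicates 1, 3 and 4). Of the 16 fits without 1 array, the call of Prss56 held in 2 (largest adjusted p = 0.0976) and that of Cebpd in 3 (0.107). The call of Slc45a2 held in 14 (0.0564).

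Between 1 month and 1 year, 18 of 24 microglia and macrophage genes and 17 of 21 interferon genes rose in wild types and 12 of 18 lens genes fell. With an estimated correlation camera did not call the lens list (adjusted p = 0.252 with an estimated correlation). The lysozyme gene Lyz2 rose by 4.46 ± 0.15, a 22.0-fold difference (adjusted p = 4.22e-10), and Lyz1 by 4.07 ± 0.20. The integrin gene Itgax rose by 5.24 ± 0.20 and S100a8 by 4.55 ± 0.71, and the proton pump gene Atp6v0d2 was at least 16-fold higher. The gamma crystallins Cryge (-13.08 ± 1.18), Crygb (-11.39 ± 1.43), Crygc (-9.83 ± 1.09), Crygf (-9.63 ± 0.88) and Crygd (-9.13 ± 1.03) fell, and Cryge and Crygb were well above background on 2 of the 4 older arrays each.

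Of 19022 genes, 2352 differed with age in wild types, 1391 higher and 961 lower, and the groups did not overlap in 18.9% of genes. Microglia genes rose in 18 of 24 members and 20 adjusted over the list alone (median 1.56, camera adjusted p = 1.82e-30, adjusted p = 0.011 with an estimated correlation), interferon genes in 17 of 21 and 20 adjusted over the list alone (1.41, camera adjusted p = 3.28e-21, adjusted p = 0.0487 with an estimated correlation) and complement genes in 12 of 16 and 13 adjusted over the list alone (1.29, camera adjusted p = 1.52e-15, adjusted p = 0.011 with an estimated correlation). Lens genes fell in 12 of 18 and all 18 adjusted over the list alone (median -5.34, camera adjusted p = 1.12e-12, adjusted p = 0.252 with an estimated correlation). The lens list mean was 2.81 ± 0.28 in the 1-month and -3.42 ± 1.57 in the 1-year wild types (SD, n = 4). The rod median was -0.02, with a mean of 0.02 (adjusted p = 0.595). The gliosis list also rose, with a list mean of -0.55 ± 0.17 in the 1-month and 0.05 ± 0.14 in the 1-year wild types (SD, n = 4). Camera called the gliosis list in all 8 fits without 1 array (largest adjusted p = 0.000454), but not with an estimated correlation. The count was 2321 with slide as a block, 189 and 725 on slides 1 and 2 alone, 1513 without wild-type 1-year replicate 1, and 409 with the RPE, melanin, matrix and endothelial covariate.

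In mutants, 13 of 20 gliosis genes and 15 of 24 microglia and macrophage genes rose with age, and 10 of 24 rod genes fell. The rod list was not called with an estimated correlation (adjusted p = 0.276 with an estimated correlation). Lcn2 rose by 3.40 ± 0.30, Edn2 by 3.32 ± 0.27, Lyz2 by 3.21 ± 0.15 and Itgax by 3.73 ± 0.20, and Atp6v0d2 was at least 9.54-fold higher. Of 19022 genes, 1274 differed, 717 higher and 557 lower. The gliosis list had 13 of 20 members higher, and adjusted over the list alone 17 higher and 1 lower (median 1.15, camera adjusted p = 1.18e-20, adjusted p = 0.0049 with an estimated correlation). Microglia genes rose in 15 of 24 and 17 adjusted over the list alone (1.01, camera adjusted p = 1.94e-29, adjusted p = 0.00565 with an estimated correlation) and complement genes in 11 of 16 and 12 adjusted over the list alone (1.02, camera adjusted p = 7.41e-19, adjusted p = 0.0049 with an estimated correlation). Rod genes fell in 10 of 24 and 18 adjusted over the list alone (median -0.29, camera adjusted p = 1.12e-10, adjusted p = 0.276 with an estimated correlation), and interferon genes rose in 8 of 21 and 9 adjusted over the list alone (0.54, camera adjusted p = 1.26e-08, adjusted p = 0.276 with an estimated correlation). The crystallins Cryge (-8.69 ± 1.18), Crygf (-8.32 ± 0.88), Crygd (-5.88 ± 1.03) and Cryga (-5.77 ± 0.95) fell. Crygb was -6.28 ± 1.43 (from -6.285), a call lost without mutant 1-month replicate 2 or 1-year replicate 2 (largest adjusted p = 0.0539). The lens list mean ranged from -0.50 to 4.35 in the 1-month mutants and from -4.05 to 1.71 in the 1-year mutants. The count was 1232 with slide as a block, 37 and 162 on slides 1 and 2 alone, 275 without the 3 arrays with the female pattern, 847, 800, 784 and 1924 without mutant 1-month replicates 1 to 4, and 838 without mutant 1-year replicate 2. The calls were 56.3% higher, but mostly lower without mutant 1-month replicate 4 (46.1% higher), with array weights (40.8%) and with the olfactory receptor covariate (40.7%), and 82.9% higher at a 2-fold minimum. Of the age calls, 479 were higher and 234 lower in both genotypes, where 52.4 and 28.1 are expected for independent lists, and 14 were opposite. Because the 2 age comparisons share each gene's variance estimate, these expected counts may be too low.

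Genes called at both ages between the genotypes numbered 50: 28 higher at both (2.35 expected for independent lists, Fisher's exact p = 1.79e-22), 20 lower at both (0.326 expected, Fisher's exact p = 1.25e-31), and Adcy7 and Gnat3 in opposite directions. Both comparisons share each gene's variance estimate, and Fisher's test takes genes as independent of each other. The expected counts may therefore be too low and the p-values too small. Omg, Prkcq, Per1, Etnppl and Egln1 were lower at both ages and Cuedc1 and Kdr higher. Of these, Omg, Per1 and Cuedc1 lie on chromosome 11 and Egln1 on chromosome 8. The other Kdr probe was 0.13 at 1 month (unadjusted p = 0.302) and 0.20 at 1 year (0.1952, unadjusted p = 0.138). Chosen after their values were seen, BC006965 was -3.59 at 1 month and -4.37 at 1 year, Myl4 1.55 and 1.37, and Gaa -1.28 and -1.39. Pnpt1 was -0.97 at 1 month, and another probe for it went the other way at both ages (0.65 and 0.90). Of the 50 genes 17 (34%) lie on chromosome 11, which holds 7.92% of the genes tested (odds ratio 6.05, Fisher's exact p = 1.36e-07), 9 of them higher and 8 lower at both ages. Chromosome 11 held 72 of the 518 calls at 1 month (13.9%, odds ratio 1.92, adjusted Fisher's exact p = 5.96e-05) and 36 of the 163 at 1 year (22.1%, odds ratio 3.35, adjusted Fisher's exact p = 2.63e-07). Chromosome 8, with 4.99% of the genes tested, held 10 of the 50 (odds ratio 4.80, adjusted Fisher's exact p = 0.00153), 9 of them in the same direction at both ages. It held 40 of the calls at 1 month (7.72%, odds ratio 1.62, adjusted Fisher's exact p = 0.0494) and 16 at 1 year (9.82%, adjusted Fisher's exact p = 0.0655). Chromosome 2, with 8.17% of the genes tested, held fewer calls at 1 month, 23 (4.44%, odds ratio 0.515, adjusted Fisher's exact p = 0.0107). These tests were chosen after the calls were seen.

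Probes placed by the design in genome regions rather than named genes gave a second view of the same chromosome. Of 13614 such probes 39 were called at 1 month, 16 of them (41.0%) on chromosome 11, and 21 at 1 year, 14 of them (66.7%) on chromosome 11, where 4.55% of the probes tested lie. Probes of 1 region are not independent. With overlapping regions counted once, 4 of the 19 loci called at 1 month and 4 of the 8 at 1 year lie on chromosome 11, which holds 80 of the 2152 tested (Fisher's exact p = 0.00448 and 0.000111). In mm9 coordinates, 4 probes at chromosome 11, 87872568 to 87880978, were higher at both ages (up to 3.44 and 3.19), and 7 probes within 112898724 to 113062945 were lower (-1.61 to -2.66 at 1 month). A probe at 69196530 to 69197001 was -3.01 at 1 month and -2.30 at 1 year (from -2.295), and 1 at 22681800 to 22707775 was 0.84 and 0.93. Outside chromosome 11, a probe at chromosome 8, 130666467 to 130821034, was 5.23 at 1 month, and 4 probes at chromosome 3, 96074625 to 96086375, were higher at both ages (up to 3.17 and 2.55).

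**Figure D5:**
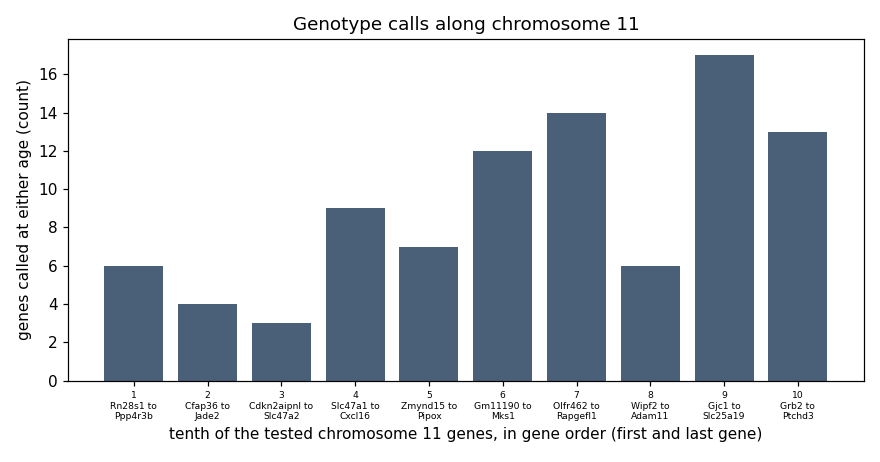
Number of genes called between genotypes at either age in each of 10 equal groups of the tested genes of chromosome 11, in gene order (GRCm38.p6). The 10 groups hold 6, 4, 3, 9, 7, 12, 14, 6, 17 and 13 of the 91 called genes.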

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

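The comparison of the interferon, microglia and rod lists with other lists, the fit without the arrays with the female pattern and the pairwise test of the RPE, melanin, matrix and endothelial lists were chosen after the result was seen, as were the chromosome tests and the fits on 1 slide and with covariates.

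At 1 month the interferon, microglia, RPE, melanin and matrix lists were all higher in the mutant, and a larger share of RPE, choroid or sclera in the mutant samples may account for part of this. The interferon median was 0.90 on slide 1, where the slide positions mix the genotypes, against 0.73 on slide 2, and 0.96 without the 3 arrays with the female pattern. Its list mean less that of the RPE, melanin, matrix and endothelial lists was -0.19 ± 0.18 in mutants and -0.64 ± 0.08 in wild types (SD, n = 4, exact permutation p = 0.0286, two-sided). The interferon list thus rose more than the mean of those lists. Whether such tissue could raise interferon genes more than those lists was not tested, so it is not excluded as the whole account. For the microglia list the same difference was -0.67 ± 0.02 in mutants and -0.69 ± 0.10 in wild types (exact permutation p = 0.83), so its rise may come with such tissue. For the RPE, melanin and matrix lists themselves a larger share of that tissue and higher expression cannot be told apart, because a single pair of lists that parts all 8 arrays has an exact permutation p of 0.0286, which becomes 0.171 over the 6 pairs, and the RPE list less the melanin list did part them (-0.29, smallest adjusted p = 0.171). A rise of macrophage, pigment cell and matrix transcripts through the mutation itself stays open and untested.

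The genotype calls gather on chromosomes 11 and 8. A single linked stretch of DNA from another strain around the mutation may account for 1 of these but not both. Whether DNA of another strain lies at more than 1 place was not tested, so such DNA is not excluded for both. The 91 called genes of chromosome 11 were spread along it, with 3 to 17 in each of 10 equal groups in gene order. Called genes lay closer together in gene order than random genes of the same chromosome, on chromosome 11 (median gap 8 against 11.5, p = 0.0035) and on chromosome 8 (6 against 14, p = 0.0001, the smallest that the 10000 permutations of each can give). That test does not separate strain DNA from other reasons for neighbouring genes to be called together. Base differences under probes cannot be told apart from changed expression, because the genes called at both ages have only 5 other probes. Of these 80% followed the first probe, which met the bound set in advance against such differences, but 5 probes are too few to rest on. An effect of the mutated gene on its neighbours was not tested, since the labels do not name the gene.

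Rod genes were lower in the mutant at 1 year, and a smaller share of retina in these samples could lower them. That predicts a like fall of other retinal neurons, and the rod mean less the means of the bipolar and amacrine lists, known by then to be higher, was -0.21 ± 0.08 in mutants and 0.25 ± 0.07 in wild types (SD, n = 4, exact permutation p = 0.0286, two-sided). Less the mean of all 5 other neuron lists it was -0.10 ± 0.13 and 0.19 ± 0.05 (exact permutation p = 0.0286), and against each alone the change was -0.22 for cones, -0.51 for bipolar, -0.40 for amacrine and -0.24 for horizontal cells (adjusted exact permutation p = 0.0358 each), but -0.09 for ganglion cells (0.83), where a like fall is not excluded. A single array is not the source, since the median without mutant 1-year replicate 2 was -0.27. A cause in the rods themselves was not tested.

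Other ways of dividing the same arrays into groups of 4 were fitted. For genes at 1 month, 2 of 35 divisions called as many as the real 518, so chance is not excluded. The other one exchanges mutant replicate 4 with wild-type replicate 4 and calls 4847, which points to a structure of the samples. The same division parts the arrays by the mean of the olfactory receptor probes. At 1 year 1 of 35 divisions called as many genes as the real 163 (highest other 0), in wild types with age 1 of 35 (real 2352, highest other 0) and in mutants with age 1 of 35 (real 1274, highest other 157). No other division reached these 3 counts, which met the bound set in advance against chance. However, 1 of 35 is the smallest share possible, and no adjustment was made for the number of counts tested. For the difference between the mutant effects 5 of 100 divisions called as many as the real 80 (highest other 2789), so chance is not excluded. Nor is it excluded for the counts of lists: 3 of 35 at 1 month (real 15, highest other 17), 15 of 35 at 1 year (real 12, highest other 19), 28 of 100 for the difference (real 12, highest other 19), 5 of 35 in wild types (real 16, highest other 20) and 2 of 35 in mutants (real 16, highest other 17). Dividing by slide called 3 genes at 1 month and 0 in the other 3 comparisons of 2 groups, with limma. With camera it called 7 lists at 1 month, 9 at 1 year, 8 with age in wild types and 9 with age in mutants.

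On some arrays a value stood far from the other 3 of its group, which chance gives in about 1 of 20 groups: 8 of 116 list values, where 5.8 are expected, and 3 of 64 gene values, where 3.2 are expected. Among list means these were wild-type 1-month replicate 1 for horizontal cells (0.29), RPE junctions (-0.36), complement (-0.92) and cholesterol synthesis (-0.35). Wild-type 1-month replicate 4 stood apart for cones (0.20), replicate 3 for endothelial cells (-0.37), mutant 1-month replicate 4 for ganglion cells (-0.14) and mutant 1-year replicate 2 for the cell cycle (0.76). Among genes these were Cxcl5 on wild-type 1-month replicate 4 (-6.33), Selenbp1 on wild-type 1-month replicate 2 (2.65) and Gaa on wild-type 1-year replicate 3 (4.51).

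The mutant effect at 1 year less that at 1 month passed the test of the difference for 12 lists. The medians were -0.33 for rods, 0.16 for amacrine cells, 0.39 for gliosis, -0.54 for the RPE list, -0.90 for melanin, -0.47 for microglia, -0.74 for interferon, -0.79 for cytokines, -0.47 for matrix, 2.91 for lens, -2.93 for erythrocytes and -0.33 for endoplasmic reticulum stress. The lens median was 1.89 (from 1.886) without mutant 1-year replicate 4, and the cytokine median -0.47 (-0.465) without mutant 1-month replicate 3. With an estimated correlation camera called 0 of these (6 lists at an unadjusted p under 0.05). The amacrine call was lost without mutant 1-month replicate 4 or mutant 1-year replicate 1 (largest adjusted p = 0.0878) and the erythrocyte call without wild-type 1-year replicate 4 (0.0671). Among named genes the differences were -2.13 for Col3a1, 1.29 for Etnppl, 1.33 for Folh1, 1.35 for Selenbp1, 3.56 for Edn2, 3.49 for Calca, 3.33 for Lcn2, 2.10 for Ccl28, -3.05 for Prss56, -1.70 for Il7r, 2.08 for Cebpd, -1.90 for Pirb, -1.82 for Col14a1 and -1.78 for Slc45a2. The calls of Prss56 and Cebpd held in only 2 and 3 of the 16 fits without 1 array.

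Probes without a gene name, which the comparisons of genes do not use, also differed between the genotypes. Of 24155 such probes 79 were called at 1 month (55 higher, 24 lower) and 48 at 1 year (34 higher, 14 lower).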

How the results depend on the processing

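Each slide alone, the covariates, and leaving out 3 arrays were chosen after the result was seen. Of 870 list results with all arrays under settings chosen in advance 745 kept direction and side of the threshold, 114 lost the call, 11 gained it and 0 turned. Leaving out 1 array at a time, also chosen in advance, gave 1392 list results more, of which 1270 kept both, 63 lost the call, 58 gained it and 1 turned. Of 2713 such results for named genes 2588 kept both, 100 lost the call, 25 gained it and 0 turned, and without 1 array 1601 of 1768 kept both, 163 lost the call, 4 gained it and 0 turned. Under the settings added later 928 of 1120 list results and 1336 of 1688 gene results kept both, and 14 list results turned. Signal near background limits the dim genes. The mark for signal well above background was set for 82.1% to 89.6% of spots. On the same arrays it was also set for 42.5% to 62.8% of the 1160 olfactory receptor probes. Whether the mark means that a gene was expressed was not tested.

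Counts of genes follow in the order 1 month, 1 year, difference, age in wild types and age in mutants, with 518, 163, 80, 2352 and 1274 as reported. Array weights gave 5058, 865, 1208, 4095 and 4817, and a 2-fold minimum, which can only lower a count, 99, 38, 50, 454 and 216. Slide 1 alone gave 1, 10, 1, 189 and 37 and slide 2 alone 17, 12, 0, 725 and 162, with 2 arrays per group. With limma, 1285 genes had an unadjusted p under 0.05 for the difference on slide 2. Covariates for lens, muscle, erythrocytes and cornea gave 1125, 31, 7, 286 and 324. Replicate number as a block gave 311, 96 and 43 for the first 3 counts. Fitting only the groups compared, with fewer arrays for the variance, gave 161 at 1 month, 86 at 1 year and 840 in mutants, and has no value for the difference, which needs all groups. A trended and robust variance gave 125 for the difference. Without 3 arrays that stood apart in lens, muscle or cornea genes the counts were 789 at 1 month and 35 for the difference. The RPE, melanin, matrix and endothelial covariate gave 22 at 1 month, 2 for the difference and 409 in wild types. Without the 3 arrays with the female pattern the counts were 133, 78, 12 and, in mutants, 275, and that pattern as a covariate gave 244 at 1 month. The olfactory receptor covariate gave 305 at 1 year, 209 for the difference and 2569 in mutants. Without 1 array the counts ran from 227 to 931, 84 to 308, 33 to 195, 1513 to 2187 and 784 to 1924. The share of calls that were higher was 74.5%, 71.2%, 33.8%, 59.1% and 56.3% as reported. At 1 month it was 43.2% with the lens, muscle, erythrocyte and cornea covariates, 35.3% on slide 2 and 18.2% with the RPE, melanin, matrix and endothelial covariate, whose own list members are among the genes tested. At 1 year it was 50.5% with the olfactory receptor covariate, 57.8% with array weights and 50% on slide 2, and ran from 61.4% to 76.8% without 1 array. In wild types it was 46.9% with the olfactory receptor covariate, and in mutants 40.7% with that, 40.8% with array weights and 46.1% without mutant 1-month replicate 4. For the difference it was 51.4% without the 3 arrays that stood apart, and 85.7% of the 7 calls with the lens, muscle, erythrocyte and cornea covariates. Except where the construction is named, the cause was not tested.

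Counts of lists were 15, 12, 12, 16 and 16 as reported. An estimated correlation gave 0, 1, 0, 3 and 3, with 4, 2, 6, 7 and 4 lists at an unadjusted p under 0.05. Fry gave 8 at 1 month, 2 at 1 year, 6 for the difference and 7 in mutants. The RPE, melanin, matrix and endothelial covariate gave 5 at 1 month and 9 in wild types, and lists that form a covariate have no value under it. Without 1 array the counts ran from 11 to 15, 8 to 15, 11 to 16, 13 to 20 and 14 to 18. The cause was not tested.

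Some list results turned direction. At 1 year the ganglion cell median ran from -0.25 to 0.024 without 1 array, the latter without mutant 1-year replicate 2, and was 0.22 on slide 2 and 0.082 without the 3 arrays that stood apart, and the cell cycle median -0.18 on slide 2 and -0.061 without those 3 arrays. On slide 2 the 1-year medians were -0.033 for muscle, -1.08 for cornea and -0.049 for cholesterol synthesis, whose difference between effects was -0.11. On slide 1 the 1-month lens median was 0.45. With the lens, muscle, erythrocyte and cornea covariates the immediate early median was 0.10 at 1 month and the cholesterol synthesis median -0.16 with age in mutants. With the RPE, melanin, matrix and endothelial covariate the complement median was -0.13 at 1 month and 0.068 for the difference. For the oxidative stress difference camera's direction turned from down to up, while the median stayed positive (0.016 and, with that covariate, 0.24). The cause was not tested.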

Other observations

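The choice of genes that follow genotype on every array was made after the result was seen.

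With age, further gene groups moved in wild types. Cytokine genes rose in 6 of 15 members and 8 adjusted over the list alone (median 0.72, camera adjusted p = 2.09e-07, adjusted p = 0.0519 with an estimated correlation). Melanin genes rose in 5 of 10 and 8 adjusted over the list alone (0.63, camera adjusted p = 4.27e-06, adjusted p = 0.316 with an estimated correlation). Genes of the RPE list rose in 4 of 15 and 9 adjusted over the list alone (0.43, camera adjusted p = 0.000305, adjusted p = 0.413 with an estimated correlation). Amacrine genes fell in 3 of 10 and 7 adjusted over the list alone (median -0.25, camera adjusted p = 0.000539, adjusted p = 0.191 with an estimated correlation). The muscle list mean was -0.70 ± 0.45 at 1 month and 0.12 ± 0.43 at 1 year (SD, n = 4). Camera called it in all 8 fits without 1 array (largest adjusted p = 0.0115), but not with an estimated correlation. In mutants camera did not call the muscle list in 3 of the 8 such fits (largest adjusted p = 0.357), nor the cornea list in 4 (0.164).

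In mutants, cone genes fell with age in 2 of 12 members, and adjusted over the list alone 6 were lower and 1 higher (median -0.32, camera adjusted p = 0.00304, adjusted p = 0.54 with an estimated correlation). Of the ganglion cell list 1 of 12 fell, also adjusted over the list alone (-0.41, camera adjusted p = 0.000363, adjusted p = 0.54 with an estimated correlation), and the median was -0.19 without mutant 1-year replicate 2. Melanin genes fell in 2 of 10, also adjusted over the list alone (-0.39, camera adjusted p = 0.00695, adjusted p = 0.54 with an estimated correlation), and the median was -0.25 without mutant 1-year replicate 2. Whether these age changes differ between the genotypes is the difference between the mutant effects, which was -0.90 for melanin (camera adjusted p = 2.67e-13, adjusted p = 0.133 with an estimated correlation), -0.14 for cones (camera adjusted p = 0.399) and -0.16 for ganglion cells (camera adjusted p = 0.179).

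The mean levels of Omg in the 4 groups were -1.18 ± 0.21 and -1.33 ± 0.18 in mutants at 1 month and 1 year, and 1.27 ± 0.17 and 0.86 ± 0.23 in wild types (SD, n = 4). Omg, Prkcq, Gaa and Cuedc1 parted the genotypes on all 16 arrays, the 3 with the female pattern and both 1-month replicates 4 included. Prkcq lies on chromosome 2. Omg, Gaa and Cuedc1 lie on chromosome 11, where genotype calls gather, so linked DNA of another strain may account for those 3. Array weights were lowest for mutant 1-month replicate 4 (0.208) and wild-type 1-month replicate 4 (0.298).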
